A study of Homo sapiens with 6 samples.

How the data were processed

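RNA sequencing of human primordial germ cell-like cells (hPGCLCs) was analysed in 6 libraries, 3 from cells with a CRISPR interference repressor and no guide RNA (empty) and 3 from cells with the same repressor and guides against the retroviral repeat LTR5Hs. The cells came from UCLA2, an established human embryonic stem cell line, and were collected on day 4 of differentiation after sorting on integrin alpha 6 and EpCAM, per the labels' protocols. Replicates 1, 2 and 3 had passage numbers 22, 25 and 26 in both groups, per the labels, which call them biological replicates.

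The deposited values are raw read counts. Per the submitters' processing notes, FastQC 0.11.8, STAR 2.7.0e, featureCounts 2.0.0, DESeq2 1.26.0 and deepTools 3.4.3 were used with the GRCh38 build, and the notes give no role or order for them. Per the file headers, the authors counted genes with featureCounts over whole gene bodies of Ensembl release 97, so that intronic reads count for the host gene. The same headers show that strand was not used, and that reads with several alignments or overlapping several genes were left out of the deposited gene counts. Of the coding genes, 1954 lie wholly under other annotated genes, and 1935 of these had 10 or fewer reads over all libraries. SOX2 and SOX15 are among them. Per the file headers, deposited repeat counts are per annotated repeat copy and count a read with several alignments in full at each one. Near-identical copies therefore share reads and are not independent. The aligner's limit on alignments per read and the treatment of duplicate reads are not given in the sources used here.

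Gene names were matched by Ensembl ID for 60261 of 60558 gene rows, with 276 more named from GENCODE release 29, which also gave gene types and coding exons. The repeat table holds 4693511 copies under 1180 subfamily names, 697 of them LTR5_Hs, the annotation's name for LTR5Hs. Gene totals ran from 24982181 to 31116370 counts per library and repeat totals from 4360126 to 4860655.

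Groups were compared with edgeR 4.0.16 (quasi-likelihood test, TMM scaling) in R 4.3.3, as LTR5Hs against empty, with Benjamini-Hochberg adjusted p under 0.05 as the threshold. Low rows were removed with filterByExpr (minimum count 10, minimum total 15) before scaling. Removing them after scaling, which was also run, tested 17551 rather than 17608 genes and called 66 genes either way. Repeat subfamilies (summed copies) and single copies were fitted the same way, with library sizes and TMM factors of the gene table. CPM are scaled by these sizes and factors, and errors are SD over 3 libraries for CPM and SE for log2 fold changes, taken as the size of the log2 fold change divided by the square root of edgeR's F.

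Genes whose start lay within 100 kb of an LTR5_Hs copy, and 25 gene lists, were tested against all other genes with camera (limma 3.58.1) at a preset inter-gene correlation of 0.01, and again with an estimated correlation. They were also tested with fry, which asks whether a set moves one way on balance and does not compare it with other genes. Calls near copies were compared by a two-sided Fisher's exact test. Shares of reads were compared by a two-sided exact permutation test, whose smallest p with 3 against 3 libraries is 0.1. Sets of genes or copies in the closing section were compared by permutation tests with 100000 resamples.

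Same-numbered libraries deviated together from their group means. The correlations across genes were 0.264, 0.104 and 0.261 for replicates 1, 2 and 3, against -0.258 to 0.0639 for the other pairs. From these correlations and the shared passage numbers in the labels, the numbers were taken to pair the libraries. Gene calls with the replicate number as a block had been seen by then and were not used for this choice. The main tests nevertheless left the pairing out, and the block was used in an alternative. No 2 libraries agreed closely enough to be the same library deposited again, since at most 68 of 13055 genes with 50 or more counts had identical counts.

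The tests were run on simulated counts, in 10 draws with 200 changed features each. Of genes changed 2-fold, 30.8% were recovered (21.0% to 45.4% between draws), and of those changed 4-fold, 74.1%, on 16938 to 16996 genes. False calls made up 6.62% of all gene calls. For subfamilies the recovered shares were 93.0% and 99.9%, on 1082 to 1085 subfamilies. For single copies they were 0.126% and 10.5%, on 57554 to 57858 copies, so that most changes of single copies were missed.

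The group comparisons, the gene lists and the rule for named genes were chosen before the data were examined. The filter order was settled after both orders had been run, and the explanations weighed in the closing section were chosen after the data had been examined. Named are 12 germ cell and sort genes, the 12 largest rises and 12 largest falls among called genes with mean CPM of at least 2 and no overlap between groups, up to 4 called members per list, up to 10 called genes within 100 kb of LTR5_Hs, a fixed set of repeat subfamilies with the 5 other largest changes in each direction, and the 8 LTR5_Hs copies with the largest fall, 7 of which are given, and 4 with the largest rise. List members given with values although they did not pass over all genes (GABRP, GATA3, ID1, ID4, FN1, KRT18, KRT8, CLDN4) were chosen after their values were seen. Alternatives left out each library in turn, used the replicate block, DESeq2 1.42.0, its size factors, other filters, windows and scalings. Limma voom with sample quality weights, fits restricted to coding genes or to genes holding no LTR5-family or HERVK-int copy, and the repeat share without each library were chosen after seeing the data.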

Results

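The transcriptome of day 4 hPGCLCs, a culture model of the first human germ cells, was measured in 3 empty and 3 LTR5Hs libraries. CRISPR interference recruits the KRAB repressor, fused to a catalytically dead Cas9, to sites chosen by guide RNAs. LTR5Hs is a long terminal repeat of the HERVK family of endogenous retroviruses. Gene counts totalled 29519835, 25585666 and 28036238 in empty replicates 1 to 3 and 24982181, 31116370 and 27686934 in the LTR5Hs ones. The library LTR5Hs replicate 2 stood apart. Mitochondrial rRNA took 34.3% of its gene counts against 18.4% to 24.2% in the other libraries, and it had reads in 545135 repeat copies against 774721 or more elsewhere.

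The first comparison asked whether the targeted repeat itself was reduced. LTR5_Hs reads fell from 520.0 ± 75.6 CPM in empty to 181 ± 31.3 CPM in LTR5Hs libraries (SD, n = 3 each). The log2 fold change was -1.52 ± 0.13 (SE; edgeR adjusted p = 8.03e-05), the smallest p of the 1091 subfamilies tested. The LTR5_Hs counts were 14425, 12624 and 17968 in empty replicates 1 to 3 and 4357, 4067 and 6232 in the LTR5Hs ones. Divided by the gene total of the library, they were 3.06 times higher in empty libraries on average, and each LTR5Hs library lay below each empty library (exact permutation p = 0.1, the smallest possible). The related repeats LTR5A and LTR5B gave log2 fold changes of -0.12 ± 0.11 and 0.10 ± 0.14, and neither passed the test. LTR5A was at -0.19 and -0.074 without empty replicates 1 and 2 and at -0.077 and -0.18 without LTR5Hs replicates 1 and 3.

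**Figure D1:**
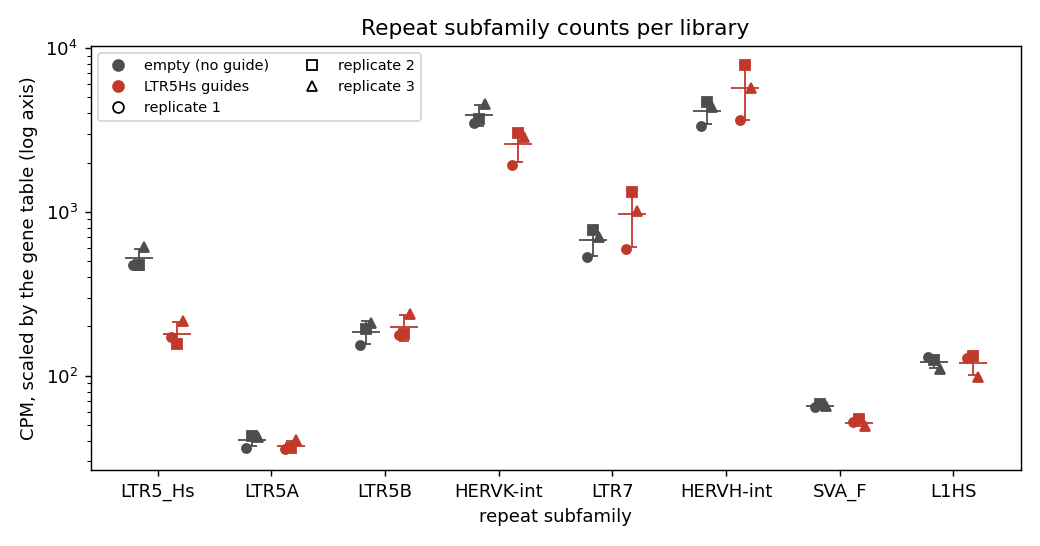
CPM of 8 repeat subfamilies on a log axis, 1 point per library, with bars for mean ± SD over 3 libraries of each group. LTR5_Hs lies at 181 ± 31.3 CPM with guides against 520.0 ± 75.6 without, while the points of LTR5A and LTR5B overlap between groups.

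Across all repeats, 3 subfamilies fell and none rose, with 51 at an unadjusted p under 0.05. Besides LTR5_Hs these were HERVIP10B3-int (-0.70 ± 0.09, adjusted p = 0.00312) and HERVK9-int (-0.62 ± 0.11, adjusted p = 0.0393), both internal parts of endogenous retroviruses. The HERVIP10B3-int call rested on the copy with the most reads, without which its log2 fold change was -0.19 (adjusted p = 0.838). The HERVK9-int call was lost without empty replicate 1, empty replicate 3 or LTR5Hs replicate 1 (adjusted p = 0.197, 0.234 and 0.164) and with scaling by the repeat table (0.176). HERVK-int, the internal part of the HERVK provirus, gave -0.59 ± 0.15 (adjusted p = 0.289), and 55.3% of its counts came from 1 copy. Without that copy it fell by 1.96 on the log2 scale (adjusted p = 8.91e-10). LTR7 and HERVH-int, active in pluripotent cells, gave 0.54 ± 0.22 and 0.47 ± 0.21 (0.25 and 0.17 without LTR5Hs replicate 2, and 0.72 for HERVH-int without LTR5Hs replicate 1), and LTR5 gave -0.84 ± 0.26, without passing. SVA_A to SVA_F lay between -0.34 and 0.06, and L1HS, L1PA2 and LTR12C at -0.027, 0.00069 and 0.015, where the LTR12C and L1PA2 values were below 0 with scaling by the repeat table (-0.032 and -0.050). With the replicate block, 23 subfamilies were called (8 rose, 15 fell), among them HERVK-int (adjusted p = 4.78e-05), LTR7 (0.00136), HERVH-int (0.0114), SVA_F (0.0421) and LTR5 (0.0467). Without LTR5Hs replicate 2, HERVK-int was called (adjusted p = 0.0355), and DESeq2 called 5 subfamilies.

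Repeats as a whole took 14.7 ± 0.522% of gene and repeat counts in empty and 14.1 ± 0.985% in LTR5Hs libraries (SD, n = 3 each; exact permutation p = 0.5). The difference of -0.57 percentage points came to -0.014 without LTR5Hs replicate 2, -0.95 without LTR5Hs replicate 1 and -0.31 without empty replicate 2, and to -0.33 for copies outside coding exons.

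Single repeat copies were compared next, to see which copies moved. Near-identical copies share reads, so counts of called copies are not counts of independent changes. A fall at a named copy may include reads from other copies. Of 72432 tested copies, 111 fell and 6 rose, and 45 of those that fell were HERVK-int and 23 LTR5_Hs. Together these made up 58.1% of the 117 calls. Of 183 tested LTR5_Hs copies, 169 had a log2 fold change below 0, with a median of -1.51. Adjusted over the list alone, 86 LTR5_Hs copies were called. The largest called fall was that of a copy on chromosome 7 (158236791 to 158237758), in the body of PTPRN2 and outside coding exons, at -3.37 ± 0.55 (adjusted p = 0.0235). A copy within SGCD on chromosome 5 (156657706 to 156658673) fell from 11.95 ± 2.18 to 1.68 ± 0.781 CPM (SD, n = 3 each; log2 fold change -2.82). A copy within MEI4 on chromosome 6 (77716945 to 77717904) gave -2.79, and a copy on chromosome 22 (18938674 to 18939641), within the genes ENSG00000283809 and ENSG00000284294, -2.93. A pair of intergenic copies on chromosome 7 (4590930 to 4591897 and 4599433 to 4600400) gave -2.82 and -2.80, and an intergenic copy on the scaffold KI270734.1 (163973 to 164940) -2.78, and all of these passed the test. No LTR5_Hs copy rose in the edgeR test or in any of 11 alternatives, DESeq2 among them.

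The number of called copies depended on single libraries. It was 44 without empty replicate 3, 67 without empty replicate 2, 71 without empty replicate 1 and 75 without LTR5Hs replicate 1, and for LTR5_Hs copies 7, 12, 14 and 10 in the same order. The PTPRN2 copy lost its call without empty replicate 2, empty replicate 3 or LTR5Hs replicate 1 (adjusted p = 0.141, 0.270 and 0.122). The first intergenic copy on chromosome 7 lost its call without any 1 of these or empty replicate 1 (adjusted p up to 0.265), and the other copy of the pair without empty replicates 1 or 3 (adjusted p = 0.0516 and 0.168).

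**Figure D2:**
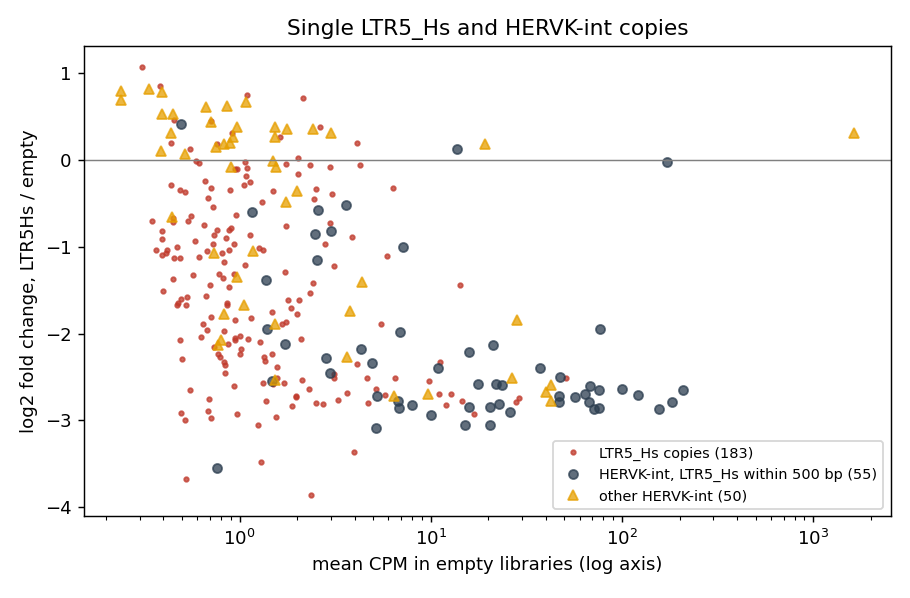
Log2 fold change (LTR5Hs against empty) of single LTR5_Hs and HERVK-int copies against their mean CPM in the empty libraries (log axis), 1 point per copy. Most of the 183 LTR5_Hs copies lie below 0, with a median of -1.51, and the HERVK-int copy with the most reads lies at 0.31.

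Among genes, 65 fell and 1 rose of 17608 tested in the main fit, which left out the replicate block, with 1399 at an unadjusted p under 0.05. With the block, 201 fell and 87 rose. TNIK, a serine/threonine kinase, was the gene that rose in the main fit, from 6.04 ± 1.16 to 16.02 ± 1.42 CPM (log2 fold change 1.41 ± 0.22, adjusted p = 0.0445). Among the falls was ST6GAL1, a sialyltransferase on chromosome 3 (186930502 to 187078553), from 473 ± 16.3 to 111 ± 22.0 CPM (-2.10 ± 0.16, adjusted p = 0.00235). PLAAT3, a phospholipase and acyltransferase, had a log2 fold change of -2.11, VSTM2B of -2.88 and NECAB1, a neuronal calcium-binding protein, of -2.99. CNR1, a cannabinoid receptor, fell from 19.3 ± 4.88 to 2.41 ± 0.962 CPM. TMEM64, TPRXL, PHF24, ANKDD1B and VSTM2B-DT had log2 fold changes of -3.51, -3.41, -2.26, -2.34 and -2.48, and the long noncoding RNA gene ENSG00000253652 of -2.73, all past the threshold. VSTM2B-DT starts beside VSTM2B, and TMEM64 beside NECAB1, on opposite strands, and counting without strand cannot separate reads that run past either start.

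Some of these genes contain the targeted repeats. SGCD, which encodes delta-sarcoglycan, fell by 2.73 on the log2 scale, and its body holds 4 LTR5-family or HERVK-int copies. These had 19802 repeat counts in the empty libraries, where SGCD had 6582 gene counts. The counts are unlike measures, since reads with several alignments count in full at each copy and are left out of gene counts. MEI4, a meiotic gene, fell by 1.95 with 3 such copies, and the beta-defensin gene DEFB107B fell by 2.699 with 5 and is uncertain, since it has a near-identical paralog. TMEM64, NLRP7, CEBPZ and ENSG00000253652 hold 3, 2, 1 and 1 such copies. In all, 17 of the 65 genes that fell hold such a copy, and 468 tested genes do.

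The number of called genes moved with the fit. The replicate block gave 87 rises and 201 falls, including all 66 genes, and DESeq2 gave 330 calls. Leaving out 1 library gave 23, 18 and 12 calls without empty replicates 1, 2 and 3, and 42, 23 and 146 without LTR5Hs replicates 1, 2 and 3. TNIK lost its call in 5 of these 6 fits (adjusted p from 0.104 to 0.222), all but that without LTR5Hs replicate 3, and so did ENSG00000253652 (0.0747 to 0.244). Without the genes holding an LTR5-family or HERVK-int copy, 36 of the 49 other called genes kept their call and no further gene was called, and TNIK was among those that lost it (adjusted p = 0.0569). TMEM64, VSTM2B-DT and PHF24 lost theirs without any 1 empty library (adjusted p from 0.0501 to 0.0895), TPRXL without empty replicates 1 or 2 or LTR5Hs replicate 2 (0.0533, 0.0708 and 0.0658), and CNR1 without empty replicates 1 or 3 (0.0571 and 0.0693). Without empty replicate 3, DEFB107B, CEBPZ, PTAR1 and LINC02754 lost theirs (adjusted p = 0.0539, 0.0524, 0.0606 and 0.0606).

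The core germ cell genes did not pass the test. Since 30.8% of simulated 2-fold gene changes were recovered, this does not show that these genes were unchanged. PRDM1, TFAP2C and SOX17, the transcription factors that specify human germ cells, gave log2 fold changes of 0.27 ± 0.15, -0.32 ± 0.19 and -0.38 ± 0.29 (adjusted p = 0.697, 0.717 and 0.782). NANOS3 gave 0.28 ± 0.20, KIT -0.19 ± 0.11 and PDPN 0.13 ± 0.12. The pluripotency factor POU5F1 was at 120 ± 5.49 CPM in empty and 82.9 ± 21.5 CPM in LTR5Hs libraries (-0.54 ± 0.18, unadjusted p = 0.018, adjusted p = 0.491), and NANOG gave -0.11 ± 0.31. The sort markers ITGA6 and EPCAM gave -0.18 ± 0.23 and 0.20 ± 0.25. The cells were sorted on both before sequencing, so a change in how many such cells formed cannot be seen here. Single libraries moved several of the log2 fold changes above. SOX17 was at -0.15 and -0.79 without LTR5Hs replicates 1 and 3 and -0.25 without empty replicate 3, TFAP2C at -0.13 and -0.51 without LTR5Hs replicates 1 and 3, and NANOS3 at 0.47 and 0.035 without LTR5Hs replicates 2 and 3. PRDM1 was at 0.17 without empty replicate 3, POU5F1 at -0.35 without LTR5Hs replicate 2, and EPCAM at 0.021 and 0.30 without empty replicates 1 and 3 and 0.43 and 0.0065 without LTR5Hs replicates 1 and 2. PDPN was at 0.086 without empty replicate 1 and 0.20 and 0.075 without LTR5Hs replicates 1 and 2. NANOG was above 0 without empty replicates 2 or 3 or LTR5Hs replicates 1 or 2 (0.034, 0.024, 0.052 and 0.028) and at -0.36 and -0.48 without empty replicate 1 and LTR5Hs replicate 3, and ITGA6 was at 0.045 and -0.43 without LTR5Hs replicates 2 and 3 and -0.29 without empty replicate 1. SOX2 and SOX15 could not be assessed, because they lie under other annotated genes and reads there were not counted.

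**Figure D3:**
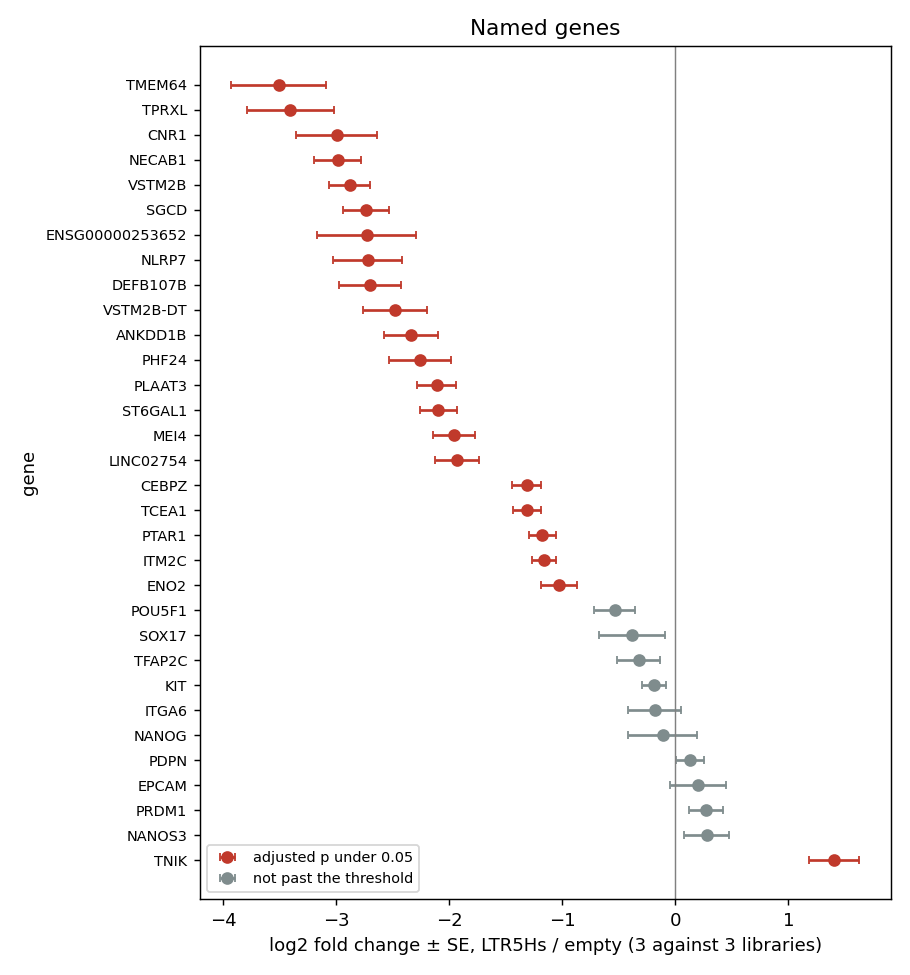
Log2 fold change ± SE (LTR5Hs against empty, 3 libraries each) of the named genes, coloured by whether adjusted p was under 0.05. The germ cell genes PRDM1 (0.27) and TFAP2C (-0.32) are among those not past the threshold, and TNIK (1.41) is the gene that rose in the fit without the replicate block.

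The next question was whether genes near LTR5_Hs copies moved. Genes starting within 100 kb of a copy fell as a group, with a median log2 fold change of -0.16 over 1223 genes against 0.017 over the other 16385 (camera p = 1.42e-13, and p = 0.00215 with an estimated correlation). The fall was graded by distance, with medians of -0.30 within 10 kb, -0.20 at 10 to 50 kb, -0.069 at 50 to 100 kb, -0.025 at 100 to 250 kb and 0.024 beyond 500 kb. Of the genes within 100 kb, 43 fell and none rose, which is 3.52% against 0.140% of the other genes (Fisher's exact p = 5.69e-34). Without empty replicates 1, 2 and 3 and LTR5Hs replicate 2 the count was 18, 12, 7 and 15, and with the replicate block 104 fell and 2 rose. Beside ST6GAL1 (36.3 kb) and PLAAT3 (85.6 kb), these included ITM2C (20.04 kb, -1.16 ± 0.11), the elongation factor gene TCEA1 (9.22 kb, -1.31 ± 0.12), CEBPZ (5.31 kb, -1.31 ± 0.13), PTAR1 (3.13 kb, -1.18 ± 0.12), LINC02754 (17.6 kb, -1.93 ± 0.20), ANKDD1B (4.67 kb), MEI4 and DEFB107B.

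Genes near other repeats showed smaller shifts. The medians were -0.016 for LTR5A, -0.021 for LTR5B, -0.0059 for the LTR7 group and -0.0064 for LTR12C, none past the adjusted threshold by camera. Genes near HERVK-int (median -0.070, adjusted p = 0.00208) and SVA (median -0.032, adjusted p = 0.0392) fell as groups by camera. Called genes, all of which fell, were more frequent near LTR5A (1.43% against 0.353% of other genes, Fisher's exact p = 0.01001), the LTR7 group (0.741% against 0.309%, p = 0.00178), LTR12C (0.657% against 0.326%, p = 0.0215), HERVK-int (2.38% against 0.346%, p = 0.000359) and SVA (0.593% against 0.228%, p = 0.000135), without adjustment over the sets, and near LTR5B there were 0 (p = 0.0759). After genes within 100 kb of LTR5_Hs were left out, Fisher's exact p was 0.318 or more for all 6 sets, and neither HERVK-int nor SVA passed by camera (adjusted p = 0.697 and 0.0555; the first had a median of 0.026 while its test direction was down). For SVA the difference of medians was -0.0661 then and -0.0716 before. The called share stayed above that of other genes for LTR5A (0.370% against 0.137%, from 1 gene), LTR12C (0.210% against 0.128%) and SVA (0.172% against 0.120%). It was 0.128% against 0.142% for the LTR7 group and 0 for LTR5B and HERVK-int, so few calls were left to compare.

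**Figure D4:**
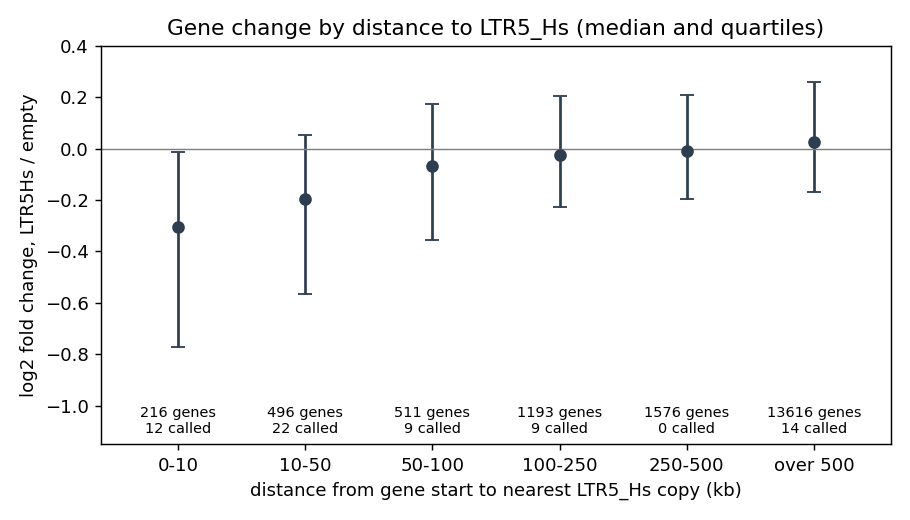
Log2 fold change (LTR5Hs against empty) of tested genes by distance from gene start to the nearest LTR5_Hs copy in kb, with points at the median and bars at the quartiles. The median runs from -0.30 within 10 kb to 0.024 beyond 500 kb.

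The gene lists asked whether germ cell, other lineage or stress programmes moved. Of 406 unique list members, 72 were not tested, and 26 lie wholly under other annotated genes. Members above or below 0 are counted among those tested. The early PGC list, with 18 of 24 members tested, did not pass, with 9 above and 9 below 0 and a median of 0.052 (camera adjusted p = 0.984). The median was below 0 without empty replicate 1 (-0.031), without LTR5Hs replicate 3 (-0.063), without the low-count filter (-0.027) and with voom (-0.016), and at 0.11, 0.16, 0.091 and 0.031 without empty replicate 3, LTR5Hs replicate 1, empty replicate 2 and LTR5Hs replicate 2. By edgeR, no member was called over all genes or adjusted over the list alone, with 4 at an unadjusted p under 0.05. By camera at the preset correlation, 8 of 25 lists passed, and none did with an estimated correlation.

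Amnion and trophoblast genes fell as a list, with 15 of 16 members below 0 and a median of -0.67 (adjusted p = 0.000205, and adjusted p = 0.712 with an estimated correlation). The median was -0.36 without LTR5Hs replicate 1 and -0.43 without empty replicate 2. GABRP gave -1.19 ± 0.38 and GATA3 -1.03 ± 0.37. BMP target genes fell, with 11 of 12 members below 0 (adjusted p = 0.000897, and adjusted p = 0.695 with an estimated correlation); ID1 gave -0.76 ± 0.30 and ID4 -0.62 ± 0.20. Both calls were lost without LTR5Hs replicate 1 (adjusted p = 0.109 and 0.0556), and no member of either was called over all genes or adjusted over the list alone. Of 25 interferon-stimulated genes listed, 13 were tested, and IFIT1, IFIT2, IFIT3, IFITM1, OAS2 and OAS3 lie under other annotated genes. The tested ones fell, with 12 of 13 below 0 (adjusted p = 0.0436, and adjusted p = 0.794 with an estimated correlation). That call was lost without LTR5Hs replicates 1 or 2 or empty replicates 1 or 3 (adjusted p = 0.134, 0.489, 0.1001 and 0.0812). Glycolysis genes fell with a median of -0.10 (adjusted p = 0.00493, and adjusted p = 0.355 with an estimated correlation), which was -0.23 without empty replicate 1, -0.19 and -0.21 without LTR5Hs replicates 1 and 3, and -0.17 with voom. ENO2, the neuronal enolase, was called (-1.03 ± 0.16) and starts 26.9 kb from an LTR5_Hs copy, 4 members were called adjusted over the list alone, and the ENO2 call was lost in each fit without 1 library (adjusted p from 0.0561 to 0.237) and without the genes holding an LTR5-family or HERVK-int copy (0.0571).

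Primed pluripotency genes rose as a list, with 13 of 14 members above 0 and a median of 0.55 (adjusted p = 0.00124, and adjusted p = 0.355 with an estimated correlation). The median was 0.93 without empty replicate 1. Endoderm genes rose, with 13 of 13 above 0 and a median of 1.06 (adjusted p = 0.00493, and adjusted p = 0.726 with an estimated correlation). They lost the call without LTR5Hs replicate 3, where the median was 0.10 (adjusted p = 0.742). Mesenchyme genes rose, with 15 of 16 above 0 (adjusted p = 0.00493, and adjusted p = 0.726 with an estimated correlation), and lost it without empty replicate 3, LTR5Hs replicate 2 or LTR5Hs replicate 3 (adjusted p = 0.0812, 0.500 and 0.169). FN1 gave 0.87 ± 0.23. Mitochondrially encoded genes rose, with 13 of 13 above 0 and a median of 0.72 (adjusted p = 7.22e-06, and adjusted p = 0.712 with an estimated correlation). Without LTR5Hs replicate 2, the library with 34.3% mitochondrial rRNA, their median was 0.21 (adjusted p = 0.0179). No member of these 4 rising lists was called over all genes or adjusted over the list alone.

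The other 17 lists did not pass (adjusted p from 0.0551 to 0.984). For the early PGC and later germ cell lists the test direction differed in sign from the median, for the cell cycle list the median was above 0 and the mean and direction below, for the WNT and epithelial lists the mean alone was below 0, and for the primitive streak list the mean alone was above 0. Adjusted over the list alone, 3 members were called in the epithelial list and 1 each in the WNT and oxidative phosphorylation lists. In the naive pluripotency list, NLRP7, an NLR-family gene of oocytes and early embryos, fell from 30.0 ± 11.2 to 4.55 ± 0.324 CPM (-2.72 ± 0.31, adjusted p = 0.0114), with 2 members called adjusted over the list alone. That call was lost without empty replicate 2, empty replicate 3 or LTR5Hs replicate 2 (adjusted p = 0.0600, 0.0606 and 0.0747). With the replicate block the naive list (adjusted p = 0.0225) and the endothelial and blood list (adjusted p = 0.00912) also passed at the preset correlation, while with an estimated correlation, run without the block, both had an adjusted p of 0.618. Other fits at the preset correlation also called the naive list (adjusted p = 0.00500 and 0.0419 without empty replicate 1 and LTR5Hs replicate 2), the endothelial and blood list (0.0466, 0.0499 and 0.0192 without empty replicates 1 and 2 and LTR5Hs replicate 2, and 0.0320 with voom), the oxidative phosphorylation list (0.00664 without empty replicate 1, 0.0296 without the low-count filter and 0.0115 with voom) and the shared pluripotency list (0.0466 without empty replicate 1). With an estimated correlation and all libraries, the last pair had an adjusted p of 0.794 and 0.951.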

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

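The fits restricted by gene type or gene body, the voom fits and the repeat share without each library were chosen after seeing the data. The LTR5_Hs subfamily fell past the threshold in all 13 alternatives run (-1.67 to -1.40), and genes near LTR5_Hs in all 18, of which fry tests the set against no change and not against other genes. Counts of called genes were 288 with the replicate block, 330 with DESeq2, 154 without the low-count filter, 36 without genes holding an LTR5-family or HERVK-int copy (all 36 among the 49 called genes that hold none), and 12 to 146 without 1 library. Subfamilies numbered 23 with the replicate block and 5 with DESeq2. Copies numbered 580 without the filter (375 rose), 333 with DESeq2 and 44 to 169 without 1 library, and LTR5_Hs copies 45 with DESeq2 and 7 to 31 without 1 library. Fewer libraries give fewer residual degrees of freedom, yet without LTR5Hs replicate 3 the called genes rose to 146. The cause of these shifts was not tested. Beyond the changes given here and beside the results, the replicate block changed no other call among the named genes, subfamilies, copies and the gene lists. Calls of list members come from the fit without the block and were not checked with it.

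Of the gene lists, 0 passed with an estimated correlation, 1 with fry and 5 to 11 without 1 library. With an estimated correlation the adjusted p was 0.355 for primed pluripotency and glycolysis, 0.726 for endoderm and mesenchyme, 0.712 for amnion and mitochondrially encoded genes, 0.695 for BMP targets and 0.794 for interferon genes. With fry, which does not compare a list with other genes, it was 0.177 for primed pluripotency, 0.593 for endoderm, mesenchyme, interferon and mitochondrially encoded genes, 0.584 for amnion and 0.502 for BMP targets. With voom it was 0.0567 for interferon genes. Without 1 library it ran from 4.61e-07 to 0.742 for endoderm, 1.18e-09 to 0.109 for amnion, 2.13e-06 to 0.500 for mesenchyme, 4.26e-08 to 0.0556 for BMP targets and 0.000153 to 0.489 for interferon genes. Primed pluripotency, glycolysis and mitochondrially encoded genes passed in each fit without 1 library (highest adjusted p = 0.0250, 0.0397 and 0.0179). All 8 lists lost their call in the camera test with an estimated correlation. The estimate was 0.959 for mitochondrially encoded genes, 0.483 for endoderm, 0.466 for amnion and 0.429 for interferon genes. It was 0.407 for mesenchyme and 0.355 for BMP targets, and the preset 0.01 was far too low for these lists if the estimates hold. For primed pluripotency it was 0.030. For glycolysis it was -0.047, below the preset 0.01, so a higher correlation does not account for its loss. Genes near LTR5_Hs had an estimate of 0.0112, yet camera p was 0.00215 against 1.42e-13 at the preset value. The runs therefore differ in more than the correlation. The 5 lists other than primed pluripotency, glycolysis and mitochondrially encoded genes depended on single libraries as well. The cause was not tested.

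Sign changes occurred for genes and subfamilies near 0 that did not pass, and for the medians of gene lists that did not pass. Without 1 library the log2 fold change ran from -0.48 to 0.052 for NANOG, -0.43 to 0.045 for ITGA6, -0.058 to 0.20 for LTR5B, -0.29 to 0.027 for SVA_E, -0.20 to 0.028 for SVA_C, -0.23 to 0.035 for SVA_A, -0.060 to 0.18 for SVA_B, -0.10 to 0.096 for L1HS, -0.036 to 0.083 for LTR12C and -0.12 to 0.11 for L1PA2. L1PA2 was at -0.0083 with the replicate block, -0.050 with scaling by the repeat table and -0.0023 without its top copy, LTR12C at -0.032 and -0.0042 in the last pair, and SVA_B at -0.021 without its top copy. Of the other values for named items, 651 kept direction and side of the threshold, 57 lost the threshold and 8 gained it. Recovery of simulated 4-fold changes was 10.5% for single copies against 74.1% for genes and 99.9% for subfamilies; how much of this comes from depth was not tested.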

Other observations

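The explanations tested below start from patterns seen in the data. Their tests were planned before the results of the tests were seen, except those of the mesenchyme, interferon and mitochondrially encoded lists, which were chosen afterwards.

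Some repeat copies moved against the main direction. Of the 6 copies that rose, singled out after their values were seen, 3 were HERVH-int, internal parts of a retrovirus active in pluripotent cells. Among the called copies that fell, 1 was HERVH-int. An intergenic HERVH-int copy on chromosome 3 (179523235 to 179525958) rose from 0.607 ± 0.097 to 5.03 ± 0.381 CPM (SD, n = 3 each; edgeR adjusted p = 0.00123), and a neighbouring pair on chromosome 9 (from 85881368 to 85884099) rose by 3.51 and 3.09 on the log2 scale. In the list of sort and epithelial genes, KRT18 gave 0.93 ± 0.17 and KRT8 0.64 ± 0.18 while CLDN4 gave -1.33 ± 0.26, with 3 of 12 members called adjusted over the list alone and none over all genes.

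Genes near LTR5_Hs copies fell. The tables argue against reads of the repeats inside counted gene bodies as the whole cause, since near genes holding no LTR5-family or HERVK-int copy also fell (median -0.13, an unadjusted p of 2.33e-11 by limma's camera), and against LTR5Hs replicate 2, without which the median of near genes was -0.15 (an unadjusted p of 7.59e-14 by limma's camera). Genes whose nearest copy had enough reads to be tested had a lower median than the rest (-0.23 over 428 genes against -0.11 over 795, permutation p = 0.00039). A lower median was predicted if transcribed copies act on their neighbours, but the comparison does not decide this. Reads at a copy can come from a host gene or from other copies, and the sets were not matched for distance to the copy. The permutation also treated genes that share a copy as independent. Reads that run on from a repeat into a neighbouring gene, and direct effects of the repressor spreading from the copy, were not separated and stay open. Of the 10 splits of the libraries, 1, the real one, gave a shift as large (0.18 against at most 0.10), and 10 splits are too few for a share under 0.05.

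Of 105 tested HERVK-int copies 45 fell, while the copy with the most reads did not pass (adjusted p = 0.948). That copy, on chromosome 22 (23538730 to 23546008) within the noncoding gene PCAT14, was at 1632 ± 159 CPM in empty and 2019 ± 493 CPM in LTR5Hs libraries. The 55 tested copies with an LTR5_Hs copy within 500 bp had a median of -2.59 against 0.029 for the other 50 (permutation p = 1e-05, the smallest possible with these resamples), which is consistent with control by the flanking repeat, although copies that share reads are not independent. A flanked copy on chromosome 3 (101692862 to 101698340) gave -0.023 ± 0.22 and is an exception. An origin in reads with several alignments alone stays open: in the gene table, which leaves such reads out, 24 genes holding a flanked copy had a median of -0.68 against -0.15 for 1205 other near genes (permutation p = 0.00017), but such genes lie at an LTR5_Hs copy, where genes had lower medians in general (-0.30 within 10 kb), so that this comparison does not decide.

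The 8 lists that passed at the preset correlation were amnion, endoderm, mesenchyme, primed pluripotency, BMP target, glycolysis, mitochondrially encoded and interferon genes, and with an estimated correlation none of them passed (adjusted p from 0.355 to 0.794). At the preset correlation and without LTR5Hs replicate 2, 6 of them passed in the same direction, which argues against this library alone for amnion, endoderm, primed pluripotency, glycolysis and BMP target genes, although the median of BMP target genes was then -0.28 against -0.43 (-0.83 without LTR5Hs replicate 3). For mitochondrially encoded genes the median without it was 0.21 against 0.72, so the library may be the source of most of that shift, and the mesenchyme and interferon lists did not pass without it (smaller adjusted p = 0.489), so for these it may be the source. The endoderm median was 1.06 with all libraries, 0.84 without LTR5Hs replicate 2 and 0.10 without LTR5Hs replicate 3. Most of the endoderm shift may therefore come from LTR5Hs replicate 3. Of the 10 splits, the real one included, 3 called 8 or more lists, with 8 for the real one and 9 for the highest other, and 10 splits are too few for a share under 0.05. A shift in the mix of sorted cells was not tested.

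The same splits gave 66 genes for the real grouping and 0 for each other, 3 subfamilies against at most 2, and 117 copies against 0, each with 1 split of 10 as large. These 10 splits cannot give a share under 0.05. In each other split both groups hold empty and LTR5Hs libraries, so a real difference between these adds to the spread within groups. Few calls there are therefore no measure of what chance alone would give. The 3 other splits that part all same-numbered pairs called 0 genes, 0 subfamilies and 0 copies, and 5, 2 and 6 lists, with shifts of near genes of 0.091, 0.058 and 0.073.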
